A study of Arabidopsis thaliana with 6 samples.

How the data were processed

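Total RNA (2 μg per labelling) came from whole Arabidopsis thaliana seedlings. Per the labels, seeds were kept for 3 days at 4 °C in darkness on medium with 1% sucrose, given 6 h of white light at 100 μmol m-2 s-1 and then grown for 60 h in darkness or in continuous red light at 24 μmol m-2 s-1. Per the labels, the 3 biological replicates of each group were grown and harvested independently, and each was hybridised to its own array, with the sample in Cy5 and dark-grown Col-0 in Cy3 on all 6 arrays and no dye swap. No array set dark Col-0 against dark Col-0.

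The deposited table holds 1 log ratio per feature and array. Values were read as log2 ratios of the sample over dark Col-0, with the direction taken from the titles and the dyes per the labels. The base of the logarithm is not stated: the values reach from -5.63 to 7.85, which log10 ratios of scanner signals could hardly span, and limma, which writes log2 ratios, is named per the submitters' processing notes without a version. Background correction, normalization within arrays, scanner and spot filters are not given in the sources used here. The medians of the 6 deposited columns were -0.00073, -0.0038 and -0.0050 for red light replicates 1, 2 and 3 and -0.0012, -0.00036 and -0.0014 for pifQ replicates 1, 2 and 3, so each array appears centred. The table holds no intensities, so spots near background or saturated could not be set apart, and the number of arrays limits the precision.

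Of 45220 features, 7440 carry 1 gene name in the platform annotation, 0 carry several and 37780 are unnamed here. All 7440 matched a protein-coding gene of the TAIR10.1 annotation by gene identifier, and the accession gave the same locus for all of them. They stand for 7234 genes, 139 of which have more than 1 feature, and features of a gene were averaged on each array. The annotation served for names and gene order only, and no coordinates are given because the build behind the features is not named. No value was missing on any array.

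Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with 1 coefficient per group over all 6 arrays so that both groups share an estimate of the spread. The 3 comparisons were red light Col-0 against dark Col-0, dark pifQ against dark Col-0, and red light Col-0 against dark pifQ. For the comparisons against dark Col-0 the mean log2 ratio was tested against 0, because the control was present only as the reference channel, and this leaves out the control's own spread as far as arrays shared a control sample. The number of dark Col-0 extracts is not given in the sources used here. Tests are two-sided, with Benjamini-Hochberg adjustment over 7234 genes and a threshold of 0.05.

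The method was tested on simulated data over the 7234 genes, with 200 genes changed per group. For red light against dark Col-0 it recovered 35.1%, 96.3% and 100% of genes changed by log2 0.5, 1 and 2, with 6.33% of calls false. For pifQ against dark Col-0 it recovered 35.7%, 98.7% and 100% (5.97% false), and for red light against pifQ 11.3%, 85.0% and 99.8% (5.51% false). The simulations gave all arrays equal, independent spread and no shared reference, so these false shares need not hold for the data. Unchanged groups against 1 reference sample on all 6 arrays, its spread assumed, gave on average 917 calls in red light and 916 in pifQ.

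Before the data were examined, 28 gene lists with 380 genes were fixed, along with the design, most alternatives and the rule for naming genes. Of these genes 41 were measured. The 7 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry (statmod 1.5.0 was installed), adjusted over these lists. The lists of mutated PIF genes, photoreceptors, light signalling regulators, carotenoid synthesis, plastid sigma factors, brassinosteroid, sugar starvation, nitrate assimilation, seed storage, storage lipid mobilisation, shoot apex and heat shock genes had no measured member, 12 lists in all. The remaining lists with 1 or 2 measured genes were counted without a test. By the rule, each comparison names the 6 largest changes per direction among genes that passed with the same sign on all arrays (for red light against pifQ, with all arrays of a group beyond all of the other), up to 4 members of each list that passed or the member with the smallest p, the 5 largest shared changes per direction and up to 5 of opposite sign. Other genes are named where they complete a small count or a family and were chosen after their values were seen.

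Overlap between the comparisons against dark Col-0 was set beside independent lists and beside 50 simulations each of unchanged groups under 2 models of a shared reference. The alternatives were centring on the median, scaling to the same spread, quantile normalization, features without averaging, genes with 1 feature only, leaving out the genes whose ratios stayed nearest 0 on all arrays, a robust prior, array weights, fits on the tested group alone, fixed and random replicate blocks, other thresholds, and each array left out in turn. Removing a smooth position trend from each array (170 features a row, lowess span 0.1) and leaving out genes within 250 annotated genes of the mutated loci were added after seeing the data, as were the gene families of the closing section.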

Results

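Transcript levels were measured in Arabidopsis thaliana seedlings of 60 h on 6 two-colour arrays. Of these, 3 held Col-0 wild type grown in red light that stayed on, at 24 μmol m-2 s-1, and 3 held the pifQ mutant grown in darkness. Each array set its sample (Cy5) against dark-grown Col-0 (Cy3), so every value is a log2 ratio over dark-grown Col-0. The pifQ mutant lacks PIF3, PIF4, PIF1 (PIL5) and PIF5 (PIL6), bHLH transcription factors that bind light-activated phytochrome and keep seedlings in the dark-grown form. The 7440 features that carry a gene name stand for 7234 genes, and errors below are SD over the 3 arrays of a group unless another is named. None of the 4 mutated PIF genes has a named feature here, so the mutant could not be checked by its own transcripts. The base of the logarithm is not stated in the sources used here and was taken as 2, on which every fold size below rests.

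The arrays of a group resembled each other to different degrees. Across genes, the red light arrays correlated with each other at r = 0.812 to 0.913, and genes are not independent replicates. The pifQ replicates 1 and 2 correlated at 0.615. The pifQ replicate 3 correlated with them at 0.506 and 0.423, less than with red light replicates 1, 2 and 3, at 0.695, 0.593 and 0.601. The 7 genes spotted 10 times or more had a mean SD between their spots of 0.049, 0.058 and 0.065 on the red light arrays, 0.177 and 0.234 on pifQ replicates 1 and 2, and 0.068 on pifQ replicate 3.

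Relative to darkness in Col-0, red light raised every measured antenna, electron transport, Calvin cycle and photorespiration gene (3 of 3 in each list) and 5 of 7 tetrapyrrole genes, and lowered 4 of 5 cell wall and 2 of 3 auxin genes. The antenna, electron transport, Calvin cycle and photorespiration lists hold 21, 34, 20 and 13 genes. The measured antenna genes are all LHCB4 genes, and the other antenna genes of the list were not measured. No list as a whole passed with an estimated correlation, the smallest adjusted p being 0.221. With fry, which tests a list on its own and not against other genes, 7 lists passed. LHCB4.1, a minor antenna protein of photosystem II, rose 16.5-fold (log2 4.04 ± 0.32). RCA, the activase of Rubisco, rose 12.9-fold (log2 3.68 ± 0.08), and DFR, the dihydroflavonol reductase of anthocyanin synthesis, rose 20.2-fold (log2 4.34 ± 0.30). XTH19, a xyloglucan-modifying enzyme of the cell wall, was 4.48-fold lower (log2 -2.16 ± 0.38). IAA29, an auxin-responsive Aux/IAA repressor, was 3.31-fold lower (log2 -1.73 ± 0.08). By limma with Benjamini-Hochberg adjustment, 2731 of 7234 genes (37.8%) passed an adjusted p of 0.05, 1360 higher and 1371 lower, of which 456 and 259 changed at least 2-fold.

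Among named genes, the largest increases were in AT3G28220 (log2 5.02 ± 0.27, adjusted p = 6.71e-07), the lipid transfer protein-like gene AT5G48490 (log2 4.53 ± 0.33) and the methionine sulfoxide reductase gene MSRB6 (log2 4.34 ± 0.27). Next came DFR (adjusted p = 9.06e-06), AT1G70820 (log2 4.13 ± 0.27) and ECS1 (log2 4.06 ± 0.33). The largest decreases among them were in AT5G04120 (log2 -4.16 ± 0.16, adjusted p = 6.71e-07), AT5G02540 (log2 -3.64 ± 0.16), AT4G11610 (log2 -3.56 ± 0.35), AT4G35720 (log2 -3.48 ± 0.36) and the germin-like genes AT5G39150 (log2 -3.60 ± 0.73) and AT5G39180 (log2 -3.45 ± 0.70). These germin-like genes are near-identical copies, and their probes may not tell them apart.

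All 3 measured antenna genes rose in red light, with LHCB4.2 at 6.31-fold (log2 2.66 ± 0.24) and LHCB4.3 at log2 0.58 (± 0.22, adjusted p = 0.0308), and all 3 passed when adjusted over the list alone. The 3 measured photosystem and electron transport genes also rose (3 adjusted over the list alone). PSBW and PSBY, small subunits of photosystem II, stood at log2 3.98 ± 0.36 and 3.11 ± 0.49, and ATPC1, the gamma subunit of the chloroplast ATP synthase, at 2.63 ± 0.12. The 3 Calvin cycle genes rose, with SBPASE at log2 1.34 ± 0.32 and PRK at 0.94 ± 0.21 beside RCA. So did the 3 photorespiration genes HPR1 (log2 1.58 ± 0.17), GLDT (0.80 ± 0.20) and GLYK (0.51 ± 0.05). Each of these lists also had 3 calls adjusted over the list alone. Of 7 tetrapyrrole genes, 5 rose, and 5 passed adjusted over the list alone. Among them were the uroporphyrinogen decarboxylase genes HEME1 (log2 1.78 ± 0.17) and HEME2 (1.60 ± 0.21), the magnesium chelatase gene CHLI2 (1.54 ± 0.31) and the methyltransferase gene CHLM (1.53 ± 0.12). Against all other genes, camera placed the antenna (adjusted p = 0.00499), electron transport (0.00249), Calvin cycle (0.00851), photorespiration (0.0172) and tetrapyrrole (0.00499) lists higher. With an estimated correlation none of these calls held, at adjusted p = 0.221 for antenna and for electron transport, 0.269 for Calvin cycle, 0.277 for photorespiration and 0.277 for tetrapyrrole genes.

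Of 5 measured cell wall genes 4 fell in red light: XTH19, XTH33 (log2 -1.63 ± 0.31), and the expansin genes EXPA4 (-0.96 ± 0.52) and EXPA8 (-0.82 ± 0.20), with 4 calls adjusted over the list alone. Camera placed this list lower at adjusted p = 0.0226, and at adjusted p = 0.221 with an estimated correlation. Of 3 auxin genes, IAA29 and the homeodomain gene HAT2 (log2 -1.29 ± 0.14) fell, 2 calls also adjusted over the list alone, while the list as a whole had a camera adjusted p of 0.067. The gibberellin receptor genes GID1B (log2 -0.66 ± 0.36) and GID1C (-0.75 ± 0.11) and the ethylene transcription factor gene EIN3 (-0.53 ± 0.24) fell, in lists with 2 and 1 measured genes. PIF7, a PIF that the mutant keeps, rose 6.31-fold (log2 2.66 ± 0.17). UGT78D2, a flavonoid glucosyltransferase gene, rose 5.30-fold (log2 2.41 ± 0.04). The clock gene GI rose (log2 0.70 ± 0.09), and so did FAMA, a guard cell transcription factor gene (log2 0.86 ± 0.05). The root marker EXPA18 had a log2 ratio of -0.21 ± 0.41 (adjusted p = 0.331), and the cold-regulated gene COR47 had -0.29 ± 0.19 (adjusted p = 0.263). EF1A, 1 of 2 measured reference genes, rose 5.18-fold (log2 2.37 ± 0.25); it belongs to a family of near-identical copies, so which copy changed is uncertain. The ratio was tested against 0, which leaves out the spread of the dark Col-0 control as far as arrays shared a control sample. Without red light replicate 1, 781 genes were called higher and 651 lower, and without red light replicate 2, 881 and 807. Of 51 named calls, 11 ended without some array, at adjusted p = 0.0501 to 0.153, those of LHCB4.3, PRK, GLDT, GLYK, EXPA4, EXPA8, GID1B, EIN3, AT2G42770, AT2G25450 and AT3G62460. Quantile normalization ended those of LHCB4.3 (log2 0.54, adjusted p = 0.0862), PRK (0.78, 0.0801), GLYK (0.46, 0.0619), EXPA8 (-0.74, 0.0643), EXPA4 (-0.87, 0.0588) and AT2G25450 (0.54, 0.072).

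In darkness, LHCB4.1, PSBW and RCA were higher in the pifQ mutant than in Col-0, and IAA29 and several genes close to PIF4, such as AT2G42780, were lower. LHCB4.1 was 5.27-fold higher (log2 2.40 ± 0.35), RCA 3.63-fold higher (log2 1.86 ± 0.84) and IAA29 2.92-fold lower (log2 -1.55 ± 0.56). By limma, 841 of 7234 genes (11.6%) passed, 332 higher and 509 lower, of which 80 and 81 changed at least 2-fold. These tests share 1 estimate of spread with the red light arrays, which resembled each other more than the pifQ arrays did. With the spread of the pifQ arrays alone, 217 genes were called higher and 226 lower. Simulated unchanged groups gave 916 pifQ calls on average where 1 reference sample, its spread assumed, served all 6 arrays. They gave at most 1 where same-numbered arrays shared a reference sample. How many dark Col-0 extracts were used is not given, so the false share of the 841 calls is not known.

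Among named genes, the largest increases in pifQ were in AT5G48490 (log2 3.12 ± 1.04, adjusted p = 0.0014), MSRB6 (3.07 ± 0.48) and the GDSL-type lipase genes AT1G29660 (2.59 ± 1.12) and AT4G28780 (2.56 ± 0.24). They were followed by AT1G21500 (2.46 ± 1.24) and LHCB4.1. The largest decreases among them were in AT2G42780 (log2 -4.59 ± 0.95, 24.1-fold, adjusted p = 0.000131), AT2G43590 (-2.70 ± 0.87), AT4G35720 (-2.49 ± 0.43), AT2G42770 (-2.42 ± 1.46), AT2G42270 (-2.40 ± 0.34) and AT5G04120 (-2.36 ± 0.28).

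Of the 3 antenna genes, LHCB4.1 and LHCB4.2 (log2 1.95 ± 1.00) rose in pifQ, and LHCB4.3, at -0.42 ± 0.48, passed only when adjusted over the list alone, where 3 of 3 did. All 3 electron transport genes rose, PSBW at log2 2.00 ± 0.86, PSBY at 1.66 ± 0.88 and ATPC1 at 1.39 ± 0.78 (3 adjusted over the list alone), while RCA was the 1 Calvin cycle gene that passed, also adjusted over the list alone. Of 7 tetrapyrrole genes 4 rose, HEME1 (log2 1.26 ± 0.85), CHLI2 (1.09 ± 0.49), HEME2 (0.98 ± 0.63) and CHLM (0.91 ± 0.66), and 5 passed adjusted over the list alone. No photorespiration gene passed, with HPR1 at log2 0.61 ± 0.59 (adjusted p = 0.0803), although 1 did adjusted over the list alone. Camera placed the antenna (adjusted p = 0.0233), electron transport (0.00033), Calvin cycle (0.0233) and tetrapyrrole (0.000165) lists higher, and gave adjusted p = 0.131 for photorespiration. With an estimated correlation none held, at adjusted p = 0.253 for antenna, electron transport and tetrapyrrole genes and 0.276 for the Calvin cycle. With fry 3 lists passed: antenna (adjusted p = 0.0266), electron transport (0.0317) and cell wall (0.0477, lower).

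On pifQ replicate 3, all 19 measured genes of the antenna, electron transport, Calvin cycle, photorespiration and tetrapyrrole lists had lower ratios than on replicates 1 and 2. Their medians were log2 1.25, 1.44 and 0.20 on pifQ replicates 1, 2 and 3. RCA, for example, stood at 2.44, 2.25 and 0.90, and PRK at 0.63, 0.62 and -0.72.

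**Figure D1:**
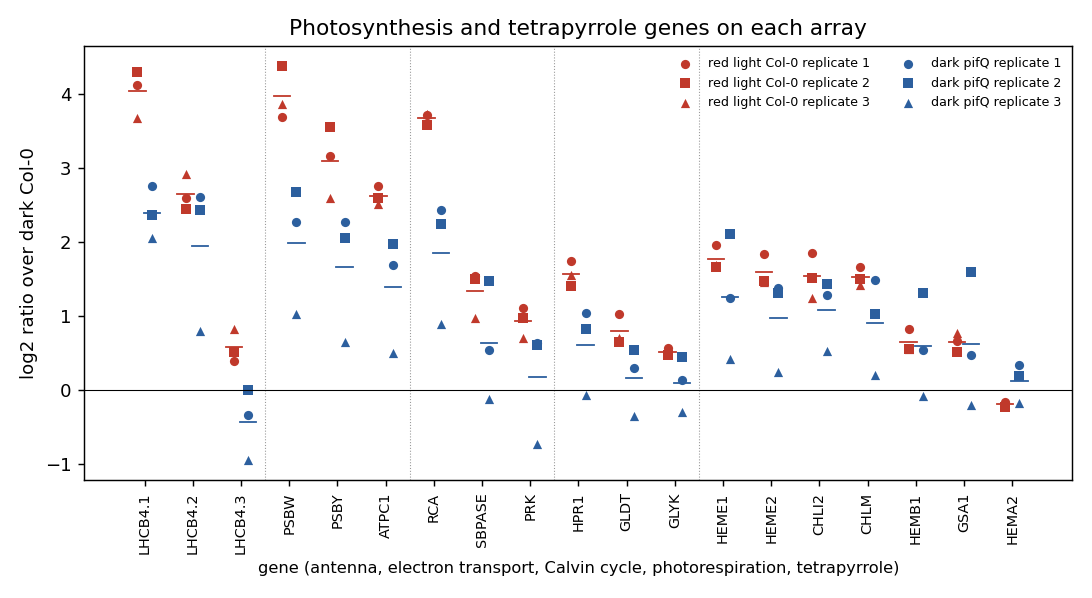
Log2 ratios over dark Col-0 (vertical axis) of the 19 measured photosynthesis and tetrapyrrole genes (horizontal axis, grouped by list) on each array, red for red light Col-0 and blue for dark pifQ, with circles, squares and triangles for replicates 1, 2 and 3 and short lines for group means. On pifQ replicate 3 all 19 genes lie below the other pifQ arrays.

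Of the cell wall genes, XTH33 (log2 -0.97 ± 0.47) and XTH19 (-0.73 ± 0.43) fell in pifQ, 2 of 5 measured and 2 adjusted over the list alone, and camera gave this list an adjusted p of 0.0694. IAA29 was the 1 auxin gene of 3 that fell, also adjusted over the list alone (camera adjusted p = 0.22). GID1C fell (log2 -0.48 ± 0.18), and 2 of 2 gibberellin genes passed adjusted over the list alone. PIF7 rose 1.36-fold (log2 0.44 ± 0.11, adjusted p = 0.0392), GI fell (log2 -0.44 ± 0.20, adjusted p = 0.0429) and EF1A rose 2.96-fold (log2 1.57 ± 0.44). DFR (log2 -0.56 ± 0.64, adjusted p = 0.138), EIN3 (-0.28 ± 0.22), FAMA (0.19 ± 0.47), EXPA18 (0.23 ± 0.13) and COR47 (-0.35 ± 0.55) did not pass. These ratios too were tested against 0, and without pifQ replicate 1 the calls numbered 94 higher and 136 lower. Without pifQ replicate 2 they numbered 110 and 178, and without red light replicate 1, 221 and 265. Of 34 named calls 16 ended without some array, at adjusted p = 0.0516 to 0.195: all 4 tetrapyrrole calls and those of LHCB4.2, PSBY, ATPC1, XTH19, XTH33, GID1C, GI, PIF7, AT1G21500, AT2G25450, AT2G44370 and AT3G62460. In contrast, LHCB4.1, PSBW, RCA, IAA29 and MSRB6 were among the 18 that passed without each array.

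Many genes were called in the same direction in red light Col-0 and in dark pifQ, and most of these were farther from 0 in red light. Ranked by the smaller of the 2 changes, AT5G48490, MSRB6, AT1G29660, AT4G28780 and AT1G21500 had the largest shared increases. For instance, AT4G28780 stood at log2 3.92 ± 0.18 in red light and 2.56 ± 0.24 in pifQ. By the same ranking, AT4G35720, AT5G04120, AT3G54830, AT5G02540 and AT4G30180 had the largest shared decreases. Examples are AT3G54830 at log2 -2.04 ± 0.07 in red light and -2.07 ± 0.15 in pifQ, and AT4G30180 at -2.0 ± 0.37 and -2.24 ± 0.20. In all, 302 genes were called higher in both and 390 lower in both, and 8 were called with opposite signs. Without pifQ replicate 1 the counts higher, lower and opposite were 85, 118 and 1, and without pifQ replicate 2, 104, 158 and 4. Without red light replicate 1 they were 188, 172 and 2, without red light replicate 2 there was 1 of opposite sign, without red light replicate 3, 4, and without pifQ replicate 3, 242 were lower.

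Of the 456 genes at least 2-fold higher in red light, 425 had a ratio above 0 in pifQ and 203 were called higher there, and their median log2 ratio was 1.38 in red light and 0.63 in pifQ. Of the 259 genes at least 2-fold lower, 246 had a ratio below 0 in pifQ and 141 were called lower, with medians of -1.31 and -0.65. Over all genes, 75.2% had the same sign in both groups. Simulated unchanged groups gave 77.0% on average where 1 reference sample served all 6 arrays, and 66.8% where same-numbered arrays shared a reference sample. Picking genes by their red light values favours larger red light medians, so genes were also picked by pifQ, after the values were seen. Of the 80 genes at least 2-fold higher in pifQ, 61 were farther from 0 in red light (medians 2.07 in red light and 1.37 in pifQ), and of the 81 at least 2-fold lower, 51 were (medians -1.70 and -1.30). Among the 692 genes called in both in 1 direction, 516 were farther from 0 in red light.

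Both comparisons have dark Col-0 as reference, which can raise their overlap with no effect at all where arrays shared a reference sample. Independent lists of these sizes would share 62.4 higher and 96.5 lower genes. Across genes the mean ratios correlated at r = 0.728 (Spearman rho = 0.694) with a covariance of 0.183. Simulated unchanged groups gave r = 0.501, a covariance of 0.0117 and at most 1 gene called higher and 0 lower in both where same-numbered arrays shared a reference sample. They gave r = 0.749, a covariance of 0.0697 and on average 222 genes higher and 221 lower in both where 1 reference sample served all 6 arrays, so the covariance exceeded the simulated values by 0.171 and 0.113. How many dark Col-0 extracts were used is not given in the sources used here, the reference could not be split, and part of the overlap may come from it. Same-numbered arrays of the groups correlated at a mean r of 0.548 and differently numbered ones at 0.583.

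**Figure D2:**
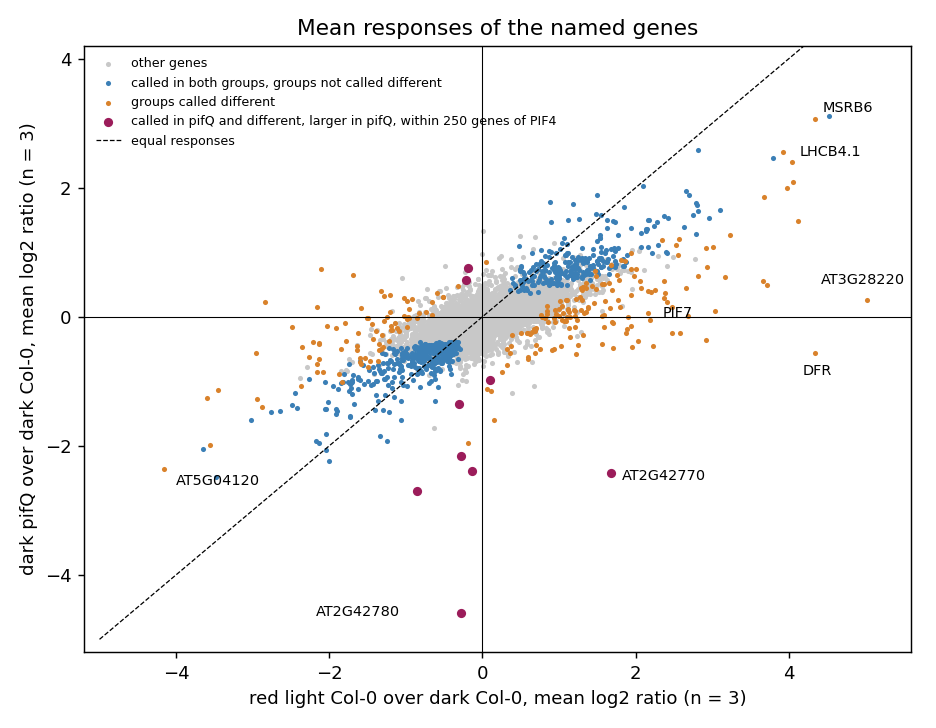
Mean log2 ratio over dark Col-0 of each of 7234 genes in red light Col-0 (horizontal axis) and in dark pifQ (vertical axis), 3 arrays each. Blue points were called in both groups and not between them, orange points were called between the groups, purple points are the 9 genes called in pifQ and between the groups, with the larger change in pifQ, that lie within 250 annotated genes of PIF4, and the dashed line marks equal responses; MSRB6 lies at 4.34 and 3.07, DFR at 4.34 and -0.56.

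DFR, AT5MAT and UGT78D2, genes of anthocyanin and flavonoid synthesis, were higher in red-light-grown Col-0 than in dark-grown pifQ, the comparison that the series names. DFR was 29.8-fold higher in red light (log2 4.89, SE 0.31, adjusted p = 0.000156), the anthocyanin malonyltransferase gene AT5MAT 9.71-fold higher (log2 3.28, SE 0.29) and UGT78D2 4.54-fold higher (log2 2.18, SE 0.21). None of them passed in pifQ against dark Col-0, where UGT78D2 had a log2 ratio of 0.22 ± 0.39 and AT5MAT of -0.37 ± 0.57. PIF7 was 4.65-fold higher in red light (log2 2.22, SE 0.16), LHCB4.1 3.12-fold (log2 1.64, SE 0.23), PSBW 3.97-fold (1.99, SE 0.39) and RCA 3.54-fold (1.82, SE 0.36), and XTH19 was 2.71-fold lower (log2 -1.44, SE 0.26). By limma 243 of 7234 genes (3.36%) passed, 159 higher and 84 lower in red light, of which 114 and 50 differed at least 2-fold. A constant dye effect cancels in this difference, and the reference cancels only where the same dark Col-0 sample served both groups. The groups differ in both light and genotype, and no pifQ seedlings grown in red light were measured. A difference between them therefore cannot be credited to light or genotype alone.

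The other largest differences among named genes were AT3G28220 (log2 4.76, SE 0.23, adjusted p = 5.73e-05), AT2G42780 (4.31, SE 0.40), AT2G42770 (4.1, SE 0.60) and AT3G28270 (3.22, SE 0.19), higher in red light. Lower were AT3G02620 (-3.07, SE 0.20), AT2G16005 (-2.85, SE 0.50), the germin-like genes AT5G39160 (-2.40, SE 0.24) and AT5G39150 (-2.34, SE 0.34), AT2G44370 (-2.34, SE 0.21) and AT1G45015 (-2.33, SE 0.27). AT2G42780 differed because of pifQ, at log2 -4.59 there and -0.28 in red light. Of the 243 genes, 103 were called higher and 56 lower in red light alone, 14 were called in pifQ alone and 70 in both.

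Genes whose change in pifQ was the larger and passed both in pifQ and between the groups numbered 21, and 9 of them lie within 250 annotated genes of PIF4, among them AT2G42270, AT2G42770, AT2G42780 and AT2G43590. This set was defined after the values were seen.

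**Figure D3:**
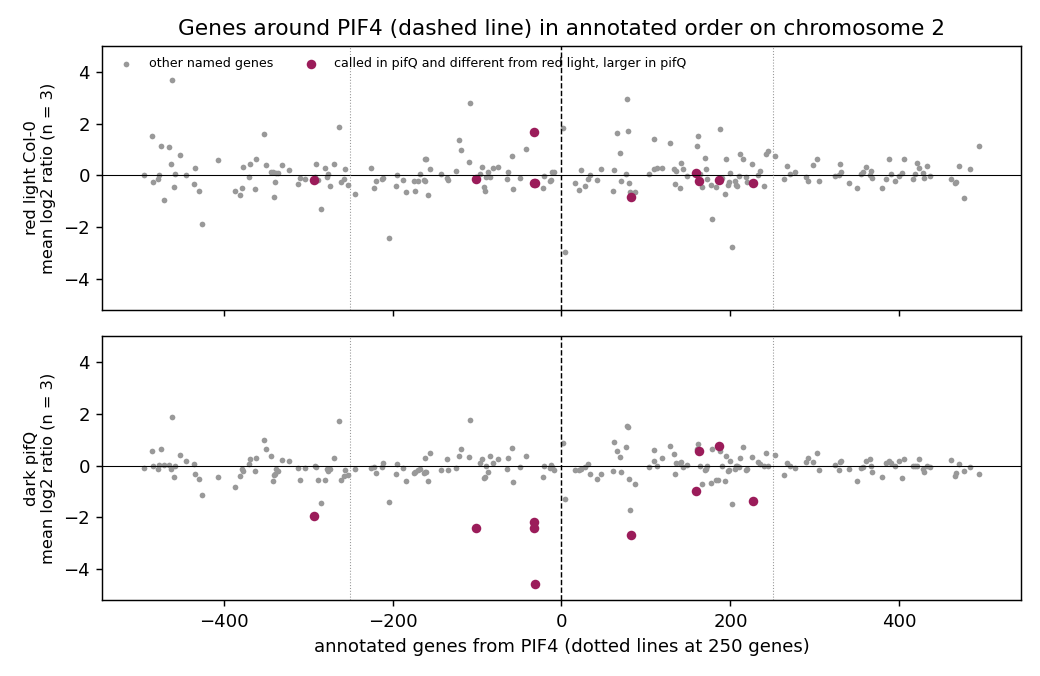
Mean log2 ratio over dark Col-0 (vertical axes, 3 arrays each) of named genes within 500 annotated genes of PIF4 on chromosome 2, by their place in gene order (horizontal axis), in red light Col-0 (upper panel) and dark pifQ (lower panel). Purple points passed in pifQ and between the groups with the larger change in pifQ; AT2G42780 lies at -0.28 in the upper and -4.59 in the lower panel.

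The antenna and electron transport lists had 1 call of 3 each (2 and 3 adjusted over the list alone), and the Calvin cycle 1 of 3 (1 adjusted over the list alone). The cell wall list had 1 of 5 (4 adjusted over the list alone), and the photorespiration list 0 of 3 (2 adjusted over the list alone), with HPR1 at log2 0.97 (SE 0.28, adjusted p = 0.108). Camera placed the antenna, electron transport (adjusted p = 0.00816 each), Calvin cycle and photorespiration lists (0.0268 each) higher and the cell wall list (0.0268) lower in red light. With an estimated correlation none held, at adjusted p = 0.288, 0.288, 0.315, 0.315 and 0.288. The antenna, electron transport, Calvin cycle and photorespiration genes all had their lowest pifQ ratio on replicate 3, which widens their gap to red light, and without this array 4 lists passed. The tetrapyrrole list had no call (CHLM log2 0.62, SE 0.30, adjusted p = 0.312) and a camera adjusted p of 0.339. The auxin list had none, with HAT2 at log2 -1.02 (SE 0.24, adjusted p = 0.0578) and a camera adjusted p of 0.0922, and 1 of 3 passed adjusted over the list alone. GI differed by log2 1.14 (SE 0.16, adjusted p = 0.00992), whereas FAMA (0.67, SE 0.23), GID1C (-0.26, SE 0.16), EIN3 (-0.25, SE 0.19), EXPA18 (-0.44, SE 0.22), KIN1 (0.27, SE 0.18) and EF1A (0.81, SE 0.24) did not pass. Adjusted over the list alone, FAMA and 1 of 2 reference genes did. Quantile normalization left 62 genes higher and 20 lower and ended the calls of every list. It shrank the differences of LHCB4.1 to log2 0.22 (adjusted p = 0.698), PSBW to 0.81 (0.542), RCA to 0.73 (0.59), XTH19 to -1.03 (0.199) and AT5G39150 to -1.73 (0.0702). AT2G16005, at -2.83 (0.0852), and AT2G25450, at 1.24 (0.108), lost the call at about the same size. Without red light replicate 1 the calls numbered 45 and 16, without red light replicate 2, 71 and 34, and without red light replicate 3, 120 and 40. Without pifQ replicate 1 they numbered 63 and 18, without pifQ replicate 2, 63 and 19, and without pifQ replicate 3, 364 and 199. Of 21 named calls, those of LHCB4.1, PSBW, RCA, XTH19, GI, AT2G25450, AT2G16005, AT5G39150 and AT3G62460 ended without some array, at adjusted p = 0.0501 to 0.118.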

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

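The test of dye bias was chosen after the overlap had been seen, and the tests of a common reference sample and of other splits of the arrays were chosen before their results.

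In 8 genes the ratios of red light Col-0 and of dark pifQ over dark Col-0 passed with opposite signs, and the difference between the groups passed too. As red light minus pifQ on the log2 scale, it was 1.14 for the clock gene GI, 4.1 for AT2G42770, 1.25 for AT3G62460, 1.22 for AT2G25450, 1.07 for AT3G04140, 0.92 for AT1G32690 and 0.81 for AT5G62130, all higher in red light and lower in pifQ, and -2.34 for AT2G44370, lower in red light and higher in pifQ. Simulated unchanged groups gave 0.26 such genes on average where 1 reference sample served all arrays and 0 where same-numbered arrays shared 1. These simulations cannot test the 8 genes, because a shared reference moves both ratios the same way and no gene was changed. Once both ratios pass with opposite signs, their difference is also likely to pass. AT2G42770 and AT2G44370 lie within 250 annotated genes of PIF4, and 6 genes were called with opposite signs with genes near the mutated loci left out. The red light ratios of AT1G32690, AT3G04140 and AT5G62130 passed narrowly, at adjusted p = 0.0494, 0.0499 and 0.0465, as did the pifQ ratios of GI and AT2G25450, at 0.0429 and 0.0426. The pifQ calls of GI, AT2G25450, AT2G44370 and AT3G62460 ended without some array, as did the red light calls of AT2G42770, AT2G25450 and AT3G62460. Without pifQ replicate 1 or without red light replicate 2 only 1 gene was called with opposite signs, without red light replicate 1 there were 2, and without pifQ replicate 2 or red light replicate 3 there were 4.

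Outside the named genes, 37780 unnamed features were tested together with the named ones, 45220 in all. Of the unnamed features 6030 (16.0%, against 32.3% of named features) were called in red light against dark Col-0, 1313 (3.48% against 7.16%) in pifQ against dark Col-0 and 396 (1.05% against 1.73%) between red light and pifQ. They reached log2 7.63 in red light and 5.04 in pifQ, beyond the largest increases of named genes. Their genes are not named here.

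The 692 genes called in 1 direction in both comparisons against dark Col-0, such as MSRB6, AT4G28780 and AT3G54830, could reflect a response shared by red light and the loss of the PIF genes, or the dark Col-0 channel that both have in common. A dye bias equal on all arrays would put red light and pifQ at like distances from 0, and 74.6% of these genes were farther from 0 in red light, just short of the 75% taken as the bound against this explanation. A red light effect on top of such a bias would also raise this share, so the share cannot decide. Unchanged groups against 1 reference sample gave up to 535 genes called in both in 1 direction in 50 simulations. This is fewer than observed, but the spread of that sample was assumed. An equal dye bias and 1 reference sample for all arrays would cancel in the difference between the groups. That difference passed for 70 of the 700 genes called in both, including the 8 of opposite sign. For the genes of 1 direction that passed, this argues against an equal offset as the whole of both ratios, though quantile normalization left fewer differences. The part common to both groups may still come from such an offset, with an effect in 1 group added. With no dye swap and no array of dark Col-0 against itself, neither explanation can be told apart from a shared response, for these genes or the rest.

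Of the 10 splits of the 6 arrays into groups of 3, only 1, the real split, called as many as 243 genes between groups, and the highest of the other splits called 0. These 10 splits are too few for a share under 0.05. Each of the other splits also mixes arrays of both groups, so the difference between the groups enters its spread and few calls could arise.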

How the results depend on the processing

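Removing the position trend and leaving out genes near the mutated loci were alternatives chosen after seeing the data; the others were fixed before. Not run were the rule for missing values, as none were missing, and the filter on dim probes, as the table holds no intensities, so signal over background could not be judged. Of 123 named gene results, none reversed. Over 2542 alternative values 2317 kept their direction and side of the threshold, 214 lost the call (96 of them with an array left out) and 11 gained one. Centring on the median, a robust prior, genes with 1 feature only, removing the position trend, and leaving out genes near the mutated loci kept every count within 1.5 times.

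At an adjusted p of 0.01, 829 genes were higher and 707 lower in red light, 83 and 107 in pifQ, and 47 and 14 between red light and pifQ, with 76 higher and 87 lower in both and 0 of opposite sign, and 2 lists passed in pifQ and 2 between the groups. With a 2-fold minimum, 456 and 259 passed in red light, 80 and 81 in pifQ and 50 were lower in red light than in pifQ, with 71 higher, 62 lower and 1 of opposite sign in both. Both follow from the stricter thresholds. Over all features without averaging, 4134 and 4297 features were called in red light, 703 and 1143 in pifQ and 395 and 130 between the groups, with 581 higher, 919 lower and 18 of opposite sign in both, from more features tested.

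Array weights, which gave red light replicate 1 a weight of 5.6, raised the calls to 2161 and 2347 in red light and to 393 and 246 between the groups. Quantile normalization gave 62 and 20 between the groups, with 0 lists passing, and scaling to the same spread gave 265 higher. Leaving out the genes nearest 0 on all arrays gave 5 genes of opposite sign. With only the arrays of the tested group, 217 and 226 passed in pifQ and 1527 and 1517 in red light, with 191 lower and 4 of opposite sign in both. The main fit gives both groups 1 spread, although the pifQ arrays resembled each other less than the red light arrays did. The cause of the changed counts in this paragraph was not tested. With an estimated correlation 0 lists passed in red light, 0 in pifQ and 0 between the groups. With fry 7 passed in red light, 3 in pifQ and 0 between the groups.

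Replicate numbers gave no sign of pairing the samples. Same-numbered deviations from the group means correlated at -0.18, -0.15 and -0.17, and not every array correlated best with its own number. Differently numbered deviations correlated at -0.15 to 0.26, and no other matching of the arrays was tested. With the replicate block, 227 genes were lower in pifQ, 92 higher and 28 lower between the groups, and 183 lower and 3 of opposite sign in both. With the random replicate block (correlation -0.167), 48 were lower between the groups.

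Leaving out each array in turn, with fewer arrays in the fit, gave 781 to 1524 genes higher and 651 to 1477 lower in red light, 94 to 366 higher and 136 to 472 lower in pifQ, and 45 to 364 higher and 16 to 199 lower between the groups. In both, 85 to 314 were higher, 118 to 305 lower and 1 to 11 of opposite sign, and the correlation of the mean responses ranged from 0.630 to 0.731, lowest without pifQ replicate 3. Lists passing ranged from 6 to 7 in red light, 3 to 5 in pifQ and 4 to 5 between the groups.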

Other observations

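The families and all tests of this part were chosen after results had been seen, except the tests of position trends and of compressed ratios, which were set before their values were known.

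Of 8 measured genes of glycosyl hydrolase family 9, endoglucanases that act on cell wall glucans, 5 fell in red light, GH9B12 (log2 -2.76, SE 0.25), GH9B13 (-2.05, SE 0.14), GH9B8 (-1.71, SE 0.15), GH9C2 (-1.41, SE 0.21) and GH9C3 (-1.41, SE 0.16). The same 5 fell in dark pifQ, to log2 ratios of -1.48, -1.43, -1.10, -0.87 and -1.44. Among 28 families of 5 or more genes, camera placed this family lower in red light (adjusted p = 0.0128) and in pifQ (adjusted p = 0.0172), and with an estimated correlation at adjusted p = 0.645 and 0.664. Between red light and pifQ none of the 8 passed (camera adjusted p = 0.108).

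AT4G14090 and AT1G03940, which encode a glucosyltransferase and an acyltransferase of anthocyanins, were chosen after their values were seen, with no tally of other such genes. They rose in red light, to log2 2.59 and 2.48, beside AT5MAT at 2.91. In dark pifQ AT4G14090 had a log2 ratio of -0.25 (adjusted p = 0.431) and AT1G03940 of -0.25 (adjusted p = 0.458), and the differences of 2.84 and 2.72 passed at adjusted p = 0.00136 and 0.00183.

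Of 21 genes that passed in pifQ and between the groups with the larger change in pifQ, 9 lie within 250 annotated genes of PIF4 on chromosome 2, where 0.366 would be placed at random (permutation p = 0.0001 over 10000 random gene sets, the smallest they can give), and 0 lie as near to PIF3, PIF1 or PIF5. They are AT2G42270, the adjacent AT2G42760, AT2G42770 and AT2G42780, AT2G43590, AT2G44200, AT2G44240, BGLU15 and AT2G44770, 7 of them lower in pifQ, as were 10 of the other 12, with a median size of log2 2.16 against 0.80 in the others. A candidate explanation is a DNA difference linked to the PIF4 mutation, from a parent or from the insertion, but the count of 9 near PIF4 prompted this explanation and so cannot test it. Smooth position trends on the arrays are argued against, since all 9 stayed in the set after the trend was removed. The removal could not take out a fault at a single feature. This linked difference, by lost transcripts or altered probe sites, and a local effect of the PIF4 lesion stay open, as does any action of PIF4 on its neighbours.

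The lower ratios of the 19 photosynthesis and tetrapyrrole genes on pifQ replicate 3, with a median difference of log2 -1.09 from the mean of replicates 1 and 2 (quartiles -1.34 and -0.81), did not extend to the 456 genes at least 2-fold higher in red light, where it was -0.06 (quartiles -0.61 and 0.47). A mislabelled array is argued against by 6 genes near PIF4 that were low in the fit without this replicate, whose median on it was log2 -2.48, against -0.18, -0.28 and -0.30 on the red light arrays. Smooth position trends are argued against because the difference was -1.12 after the trend was removed. Compressed ratios are argued against because genes at least 2-fold lower in red light lay farther below 0 on this array, by a median of -0.24, and the SD over genes was 0.480 there against 0.457 and 0.477 on replicates 1 and 2. Repeated spots also varied less on replicate 3 (SD 0.068) than on replicates 1 and 2 (0.177 and 0.234), and a technical difference behind this was not tested. A difference in the seedlings, such as growth stage, may remain, and no biological explanation was tested because no group in the design stands for it.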
